A study of Mus musculus with 8 samples.

How the data were processed

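The series holds 8 microarrays of PGCs, 1 for each of 4 WT and 4 Ror2 mutant embryos at embryonic day 9.5, per the labels. Crosses of heterozygous parents on a mixed strain background gave the embryos, and an Oct4 reporter marked the PGCs. Per the labels' protocols, the posterior part of each embryo was digested with trypsin, GFP-positive cells were sorted into lysis buffer, RNA was isolated on micro columns, and the RNA was amplified and labelled with biotin using the NuGEN Ovation FFPE WTA and Encore systems. Groups, replicate numbers and somite numbers were taken from the labels.

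The deposited table gives 1 value per probe and array, and the values were taken to be on the log2 scale from their range, since the deposited table names no unit. Background correction, normalization and summarisation are not given in the sources used here. The array medians lie close together (5.37 to 5.58) without being equal, and the columns were taken as already normalized by the authors and used as deposited. The plan set before the data were examined kept deposited values if their quantiles were equal between arrays, and named quantile normalization otherwise. The distributions differ between arrays, so this condition was not met, and keeping the deposited values as the main setting departed from the plan. Quantile normalization was therefore run as an alternative to the deposited values. It called 0 gene lists for mutant against WT, and its effect is given beside the lists. No scanner values were used here, so background cannot be assessed and no detection limit is set.

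The table held 35557 probes, of which 21789 had 1 gene symbol in the platform's annotation, 1621 had several and 12147 were unnamed here. Probes with several symbols named no gene. By gene ID, 21698 of the single-gene probes matched the reference table (GRCm38.p6), and 0 symbols needed an update. The build behind the annotation is not given in the sources used here, so the reference served only to find which genes neighbour Ror2 (19853 genes had a position). Of 19938 genes tested, 999 had several probes and were represented by the probe of highest mean. Some members of the lists had no single-gene probe and were not analysed here, among them the adult globins Hba-a1 and Hbb-b1, Trp53, Cdkn1a, Bax, Gapdh, Ccnb1 and Ddx3y.

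Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means with no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior degrees of freedom were 4.48 and the median standard error of a difference was 0.17 on the log2 scale. Intervals cover 95% and rest on the limma standard errors. Differences are mutant minus WT. For single genes, errors given as SE come from limma, for list means from a linear model of the mean of each array, and for the median of small nucleolar RNAs from the spread over genes. SD is over the 4 embryos of a group. Gene lists were tested with camera at a preset correlation of 0.01 over the 34 lists with at least 3 measured genes, and again with camera at an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks whether the members move, on balance, one way. The remaining list held only Xist among the measured genes and is given as values. Slopes per somite were fitted with genotype in the model, taking the midpoint where the labels give a range.

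The groups, the tests, the alternatives, the 35 lists and the rule for naming genes were fixed before the data were examined. The lists cover germ cell identity, signalling pathways, adhesion and matrix, metabolism, cell cycle, stress, sex-linked genes and markers of neighbouring cell types, plus receptors and small nucleolar RNAs as classes of their own. The rule named up to 12 genes per direction past the threshold. As none passed, it named the 8 genes per direction of smallest p, among those with a mean above the median of all genes (5.61) and with all mutant values on 1 side of all WT values. Ror2, Ror1, Wnt5a, Axin2, Kit, Cxcr4, Pou5f1, Dppa3 and Mki67 were named whatever their values. Each list past the threshold gave its 3 members of smallest p, other lists at most 2, and the somite slope 4 genes per direction. Predicted genes counted in the totals and were not named.

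The spread of arrays was compared by an exact permutation test on the mean correlation of each array with its own group, over the 35 ways to part 8 arrays into groups of 4. Correlations across arrays were tested by exact permutation of pairings. The scripts were tested on simulated data made from the real gene means, with 200 genes changed in each of 20 simulations. The SD of each gene was its residual SD after limma had shrunk it toward a common value, so recovery in the real data may be lower. For the comparison of mutant with WT over 19938 genes, 98.8% of changes of 2 on the log2 scale were recovered, and 5.64% of calls were false. Genes were simulated independently of each other, so the simulations say nothing about false calls of lists whose members vary together. A shift of 0.15 in the oxidative phosphorylation list was called in 20 of 20 simulations. A slope of 1 per somite was recovered for 99.7% of genes. Slopes given in the results were smaller, such as 0.63 for Commd6, and this share does not hold for them.

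The alternatives were a replicate block, the somite midpoint or the Y-linked mean as a covariate, median centring, quantile normalization, filters on dim genes, the mean of all probes of a gene, all probes, a trended and robust variance model, array weights, other set tests, other windows around Ror2, and leaving out each array in turn. Added after seeing the data were the SD of the unnamed probes as a covariate and leaving out WT 3 and mutant 4 together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.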

Results

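Transcript levels were measured in primordial germ cells (PGCs), the embryonic precursors of sperm and eggs, sorted from single mouse embryos at embryonic day 9.5. At this stage PGCs leave the hindgut and move toward the gonadal ridges. Ror2 is a receptor tyrosine kinase that binds Wnt5a, and the mutant embryos were homozygous for the Y324C change in this receptor. There were 4 WT and 4 mutant embryos, each hybridised to 1 microarray, so the embryo is the replicate. The WT embryos had 25, 25, 22 and 21 somites. The mutant embryos had 24, 22 to 23, 23 and 21 to 22 somites. The group means were 23.25 somites in WT and 22.75 in mutants. Array medians over all probes ran from 5.37 to 5.58 on the log2 scale, and the number of arrays limits the precision of every comparison.

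The sex-linked transcripts placed 6 arrays on one side and 2 on the other. Xist, the RNA that silences an X chromosome in female cells, had log2 values of 7.07 in WT 3 and 6.31 in mutant 4, and from 3.50 to 4.11 in the other 6 arrays. The mean of the Y-linked genes Eif2s3y, Uty and Kdm5d was 3.74 in WT 3 and 3.71 in mutant 4, and from 7.21 to 7.73 elsewhere. Each group therefore held 1 array of high Xist and low Y-linked values.

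The main comparison asked whether PGC transcripts differ between mutant and WT embryos. Ror2 itself was at 7.69 ± 0.21 in WT and 7.81 ± 0.34 in mutants (log2, SD, n = 4 each), a difference of 0.11 with a 95% interval from -0.30 to 0.53. The allele is a single amino acid change, so the level of its transcript does not check the labels. Pou5f1 (Oct4), the pluripotency factor whose regulatory sequence drives the sorting reporter, was at 11.13 ± 0.18 in WT and 11.24 ± 0.12 in mutants. Dppa3 (Stella), a marker of the germ line, was at 11.27 ± 0.23 and 11.41 ± 0.11. Kit, the receptor that carries the Kit ligand signal to migrating PGCs, differed by 0.14 (interval -0.14 to 0.43). Cxcr4, the receptor for the guidance signal Cxcl12, differed by 0.43 (interval -0.12 to 0.97). Mki67, a proliferation marker, differed by 0.17 (interval -0.16 to 0.49).

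No gene passed the limma test: 0 of 19938 genes had an adjusted p under 0.05, and 934 had an unadjusted p under 0.05, where chance gives 996.9. This count was 1715 without WT 1 and 1664 with the SD of unnamed probes as a covariate. Of the 934 genes, 543 were higher and 391 lower in mutants. This split depended on scaling, with 611 higher and 325 lower after median centring and 518 and 449 after quantile normalization. At an unadjusted p under 0.01 there were 167 genes, against 199.38 by chance. The 4 mutant values lay wholly above or below the 4 WT values for 503 genes, which is 2.52% of those tested, where chance gives 2.86%. Simulated data of the same size had independent genes, of which 200 were changed, and shrunken SDs, so recovery in the real data may be lower. There, changes of 1 on the log2 scale were recovered for 76.8% of genes, changes of 1.5 for 95.3%, and changes of 0.5 for 5.4%. With fewer changed genes the adjustment is stricter, so these shares do not hold for a few changes of the same size.

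Among the genes of smallest p that were higher in mutants, the small nucleolar RNA Snord35b stood first. Its log2 value was 5.10 ± 0.64 in WT and 7.70 ± 0.54 in mutants, a difference of 2.60 ± 0.34 (SE) or 6.07-fold, and its limma adjusted p was 0.246. Mir6516 differed by 1.33 ± 0.25 (SE), Tprkb, a subunit of a tRNA-modifying complex, by 1.20 ± 0.25, and Pip5k1b, a phosphatidylinositol phosphate kinase, by 1.10 ± 0.21. Xiap, an inhibitor of caspases, differed by 0.94 ± 0.21, and Stx4a, a syntaxin of the plasma membrane, by 0.79 ± 0.17. Bmp7, a secreted ligand of the bone morphogenetic protein family, was at 7.24 ± 0.22 (SD) in WT and differed by 0.76 ± 0.16 (SE). Hscb, a cochaperone of iron-sulfur cluster assembly, differed by 0.72 ± 0.15.

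Among those lower in mutants, the small nucleolar RNA Snord42b differed most, by -1.48 ± 0.38 (SE). Trub1, a pseudouridine synthase, differed by -0.87 ± 0.17. Mlf1 differed by -0.65 ± 0.17, the metal ion transporter Slc39a14 by -0.64 ± 0.15, and Leng8 by -0.63 ± 0.17. Bola1 (-0.60 ± 0.15), Coa6 (-0.59 ± 0.16), a factor of cytochrome oxidase assembly, and Nrip1 (-0.59 ± 0.16), a corepressor of nuclear receptors, completed the 8. Apart from Snord35b, all of these 15 genes had a limma adjusted p of 0.973. In every one of the 16 genes the 4 mutant values lay on 1 side of the 4 WT values, which was a condition for naming them.

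**Figure D1:**
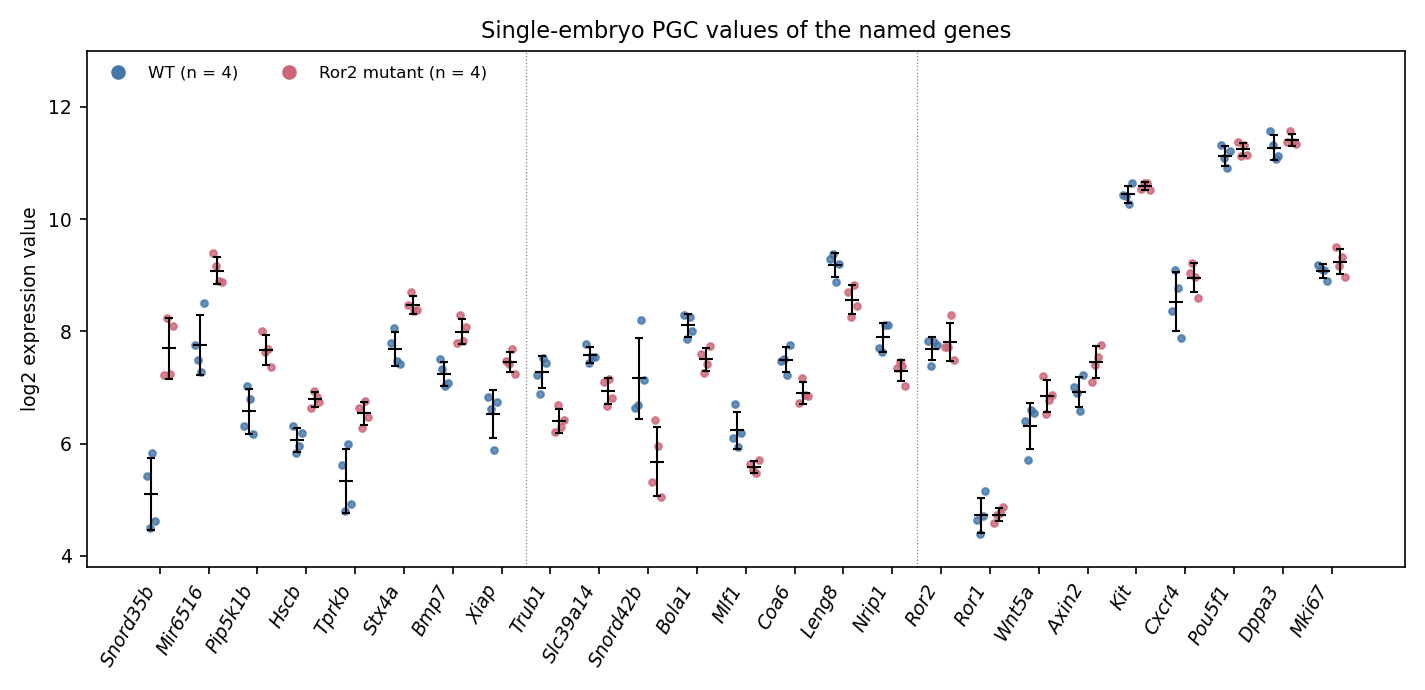
Log2 values of 16 genes of smallest p and 9 genes named in advance, 1 point per embryo (4 WT, 4 mutant), with bars for the mean ± SD of each group. Snord35b lay between 4.49 and 5.84 in WT and between 7.22 and 8.24 in mutants, while all 9 genes named in advance overlapped between the groups.

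Of the 34 gene lists tested with camera at its preset correlation, 4 passed on the deposited values. After quantile normalization, which the plan named for arrays of unequal quantiles, 0 passed. Genes of oxidative phosphorylation, which build the respiratory chain and ATP synthase, were higher in mutants as a set: 58 of 77 members lay above 0, with a median difference of 0.13 and an adjusted p of 1.55e-05. Genes of glycolysis and the hypoxia response were also higher, with 15 of 17 members above 0, a median of 0.15 and an adjusted p of 0.000393. Ribosomal protein genes were slightly higher, with 44 of 54 members above 0, a median of 0.08 and an adjusted p of 0.00208. Olfactory and vomeronasal receptor genes, which act mainly in sensory neurons, were lower as a set, with 319 of 1178 members above 0, a median of -0.08 and an adjusted p of 0.000393. The mean of this list ran from 3.57 to 3.85 over the arrays, where the median of all gene means was 5.61. Expression of these receptors thus cannot be told apart from background. With an estimated correlation within each list, all 4 lists had an adjusted p of 0.796, and fry gave 0.840, so no list was called by either.

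The single members behind these lists did not pass. In oxidative phosphorylation, 9 members were higher and 1 lower at an unadjusted p under 0.05, and 0 passed either over all genes or adjusted over the list alone. The complex I subunits Ndufs5, Ndufa9 and Ndufa2 differed by 0.87 ± 0.31, 0.56 ± 0.21 and 0.36 ± 0.13 (SE). In glycolysis and hypoxia, 4 members were higher at an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. Its enzymes Tpi1 and Aldoa differed by 0.73 ± 0.24 and 0.42 ± 0.14, and the hypoxia target Ankrd37 by 0.75 ± 0.32. No ribosomal protein gene had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Rplp0, Rpl13 and Rpl19 differed by 0.25 ± 0.13, 0.22 ± 0.13 and 0.21 ± 0.13. Of the receptor genes, 49 were lower and 4 higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Olfr1281, Olfr967 and Vmn2r121 differed by -0.65 ± 0.17, -0.65 ± 0.13 and -0.46 ± 0.13, with low group means, from 2.13 to 3.72.

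The width of the distribution differed between arrays. The SD of log2 values over genes ran from 1.77 in WT 3 to 1.95 in WT 1, and WT 3 had the lowest mean for oxidative phosphorylation (9.36), glycolysis and hypoxia (8.80) and ribosomal proteins (11.63) and the highest for the receptors (3.85). WT 3 also had the lowest mean for PGC identity and pluripotency genes (8.88, against 9.11 to 9.24 in the other 7 arrays) and the highest for primitive erythroid (5.50), macrophage (5.22), trunk mesenchyme (5.45) and tailbud progenitor (5.53) markers. Without WT 3, none of the 4 passed, with limma adjusted p-values of 0.0658, 0.0658, 0.360 and 0.0658 in the order oxidative phosphorylation, glycolysis, ribosomal proteins and receptors. The mean difference of glycolysis genes was then 0.21 ± 0.10 (SE), from 0.25 ± 0.09 with all arrays, and that of oxidative phosphorylation 0.09 ± 0.07, from 0.15 ± 0.08. That of ribosomal proteins was 0.04 ± 0.04, from 0.07 ± 0.05, and that of receptors -0.05 ± 0.06, from -0.09 ± 0.06. With WT 3 and mutant 4 both left out, 3 of the 4 passed: oxidative phosphorylation (0.000285), glycolysis (0.00138) and receptors (0.00762). After quantile normalization, which gives every array the same distribution, none passed either, with 0.144, 0.0761, 0.684 and 0.678. The ribosomal protein list also lost its call without mutant 2 (0.0680), without WT 3 and mutant 4 together (0.0800) and among genes of above-median level (0.240). Over all alternatives the adjusted p ran up to 0.840 for all 4 lists, from 1.28e-08 for oxidative phosphorylation, 2.23e-05 for glycolysis, 0.00019 for ribosomal proteins and 1.29e-05 for receptors.

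**Figure D2:**
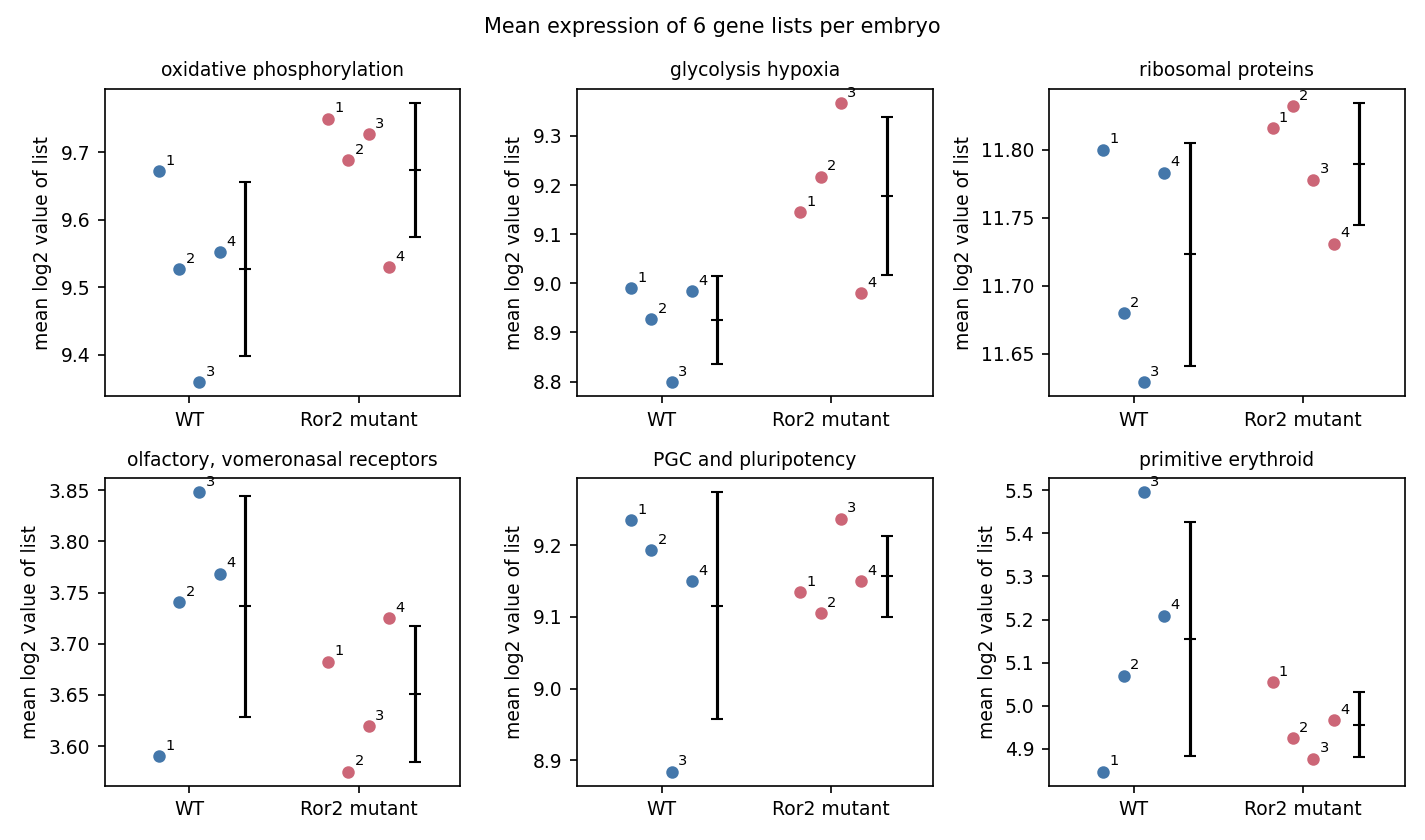
Mean log2 value of 6 gene lists in each embryo (points, numbered by replicate, 4 per group), with bars for the mean ± SD of the group. WT 3 had the lowest mean of oxidative phosphorylation genes (9.36) and the highest of primitive erythroid genes (5.50), and the groups overlapped in all 6 panels.

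The remaining 30 lists did not pass. Genes of PGC identity and pluripotency had 18 of 28 members above 0 and a median difference of 0.07 (limma camera adjusted p 0.218). The direction of this list turned without WT 3 (0.959). Alpl and Lin28a, both long-used markers of PGCs, differed by 0.27 ± 0.15 and 0.24 ± 0.20 (SE). Genes of the later germ line (adjusted p 0.715, median 0.01), led by Tex19.1 at 0.48 ± 0.22 and Dazl at 0.24 ± 0.14, and of epigenetic reprogramming (0.172, median 0.08), led by the histone methyltransferase Ehmt2 at 0.31 ± 0.14 and the DNA dioxygenase Tet2 at 0.39 ± 0.18, did not pass. The list of PGC migration and adhesion genes (0.615, median 0.04) included the matrix protein Fn1 at 0.24 ± 0.14. The actin cytoskeleton list (0.207, median 0.07) included Wasf2, an activator of actin nucleation, at 0.48 ± 0.17, and the extracellular matrix list (0.715, median -0.08) included Hspg2 at -0.26 ± 0.12.

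Signalling pathways downstream of or parallel to Ror2 were compared in the same way. Noncanonical Wnt and planar polarity genes had 24 of 38 members above 0 and a median of 0.06 (limma camera adjusted p 0.207). In this list Smurf2, a ubiquitin ligase, differed by 0.79 ± 0.23 (SE), Wnt5a by 0.53 ± 0.22 (interval 0.05 to 1.01) and Ror1 by 0.01 (interval -0.36 to 0.38). Targets of canonical Wnt signalling had 6 of 21 members above 0 and a median of -0.07 (0.524), while its member Axin2, a feedback inhibitor induced by beta-catenin, differed by 0.53 ± 0.18 (interval 0.13 to 0.93). Wnt5a and Axin2 had unadjusted limma p-values of 0.0342 and 0.0151, and both had an adjusted p of 0.973. The other pathways did not pass: Notch (adjusted p 0.499), bone morphogenetic protein (0.993), FGF and ERK (0.993) and Hedgehog (0.993) targets. Within FGF and ERK targets, the Sprouty genes Spry4 and Spry2 differed in opposite directions, by -0.75 ± 0.21 and 0.36 ± 0.18.

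Lists for growth and stress did not pass. The proteasome list lay nearest to the threshold, with 26 of 39 members above 0, a median of 0.09 and a limma camera adjusted p of 0.0513. It passed in 7 alternative settings, from 0.000659 without mutant 4 to 0.0274 on ranks, and not after quantile normalization or without WT 3. Its adjusted p was 0.796 with an estimated correlation and 0.953 with fry. Cell cycle genes had an adjusted p of 0.207 with 19 of 29 members above 0. Their direction turned without WT 3 (0.959) and after quantile normalization (0.876), and they were called higher without WT 1 (0.00617), with the somite covariate (0.0482) and with the covariate of unnamed probes (0.0157), but not with an estimated correlation (0.914). Replication histones had an adjusted p of 0.715, p53 and apoptosis genes 0.882, and immediate early genes, which respond to tissue dissociation, 0.993. Small nucleolar RNAs had an adjusted p of 0.218 and a median of -0.26, with 16 of 51 above 0. Their mean was 7.33 in mutant 2, from 6.52 to 6.73 in the other mutants and from 6.90 to 7.01 in WT. They were called lower without mutant 2 (0.00382) and among genes of above-median level (0.0139), but not with an estimated correlation (0.796). Adjusted over the list alone, 3 of them passed: Snord35b (0.000629), Snord37 (0.0439, a difference of 2.87 ± 0.71 SE) and Snord42b (0.0439), and 0 passed over all genes.

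Markers of the cells that surround PGCs were used to look for other cell types in the sort. Primitive erythroid genes had 1 of 10 members above 0 and a median of -0.19 (limma camera adjusted p 0.0971). They were called lower without WT 1 (0.0213), with the somite covariate (0.0482) and with the covariate of unnamed probes (0.0157), but not with an estimated correlation (0.796). Their mean was 5.50 in WT 3 and from 4.85 to 5.21 in the other 7 arrays. Hbb-y and Hba-x, embryonic globins, differed by -0.49 ± 0.27 and -0.42 ± 0.29 (SE). Macrophage genes had 2 of 12 above 0 and a median of -0.12 (0.207), with Tyrobp at -0.44 ± 0.19, and their mean was also highest in WT 3 at 5.22. WT 3 was also highest for the receptors (3.85), Hedgehog targets (5.65), canonical Wnt targets (6.15), extracellular matrix (6.43), Hox genes (5.09) and immediate early genes (6.44). Markers of endothelium, hindgut endoderm, urogenital mesoderm, neural tube, neural crest and surface ectoderm were not highest there. Those of endothelium, neural tube and neural crest were second highest in WT 3. Other cells in the sort of WT 3 thus cannot be told apart from the narrow distribution of this array. Tailbud progenitor (0.267), urogenital mesoderm (0.715), trunk mesenchyme (0.764), endothelium (0.764), neural tube (0.882), hindgut endoderm (0.882), neural crest (0.993) and surface ectoderm (0.993) lists did not pass. Hox genes (0.882) and Y-linked genes (0.882) did not pass either. The sign of the camera test was opposite to that of the median in the p53, neural tube, Y-linked, bone morphogenetic protein, neural crest, FGF, surface ectoderm and Hedgehog lists, and to that of the mean in the immediate early list, all far from the threshold.

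Because the embryos came from a mixed background, genes linked to Ror2 on chromosome 13 were tested as a set. The 171 genes within 10 Mb of Ror2 had a median difference of -0.02 and a camera p of 0.642. Of these genes, 4 were higher and 3 lower in mutants at an unadjusted p under 0.05, which is 4.09% (Fisher's exact test against all other genes, two-sided p = 0.856). Simc1, Lect2 and Rmi1 had the smallest p-values of this set. The other 560 genes of chromosome 13 gave a camera p of 0.837.

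The somite number stages embryos of this age, and the slope per somite was fitted with genotype in the limma model. The 4 genes of smallest p with a positive slope were Commd6 (0.63 ± 0.07 log2 per somite, SE), Gdap10 (0.56 ± 0.06), Fmr1nb (0.50 ± 0.07) and Trit1 (0.34 ± 0.05). The gap junction gene Gja1 (-0.40 ± 0.06), Hmga2 (-0.27 ± 0.05), a chromatin protein of embryonic cells, Ankrd35 (-0.27 ± 0.05) and Mir341 (-0.26 ± 0.04) had negative slopes. No gene passed: 0 of 19938 had an adjusted p under 0.05, the smallest being 0.0823 for Commd6 and Gdap10, and 1942 had an unadjusted p under 0.05, of which 1000 were positive and 942 negative, where chance gives 996.9. With the SD of unnamed probes as a covariate that count was 708. This SD was 2.307 and 2.304 in the WT embryos of 25 somites and from 2.313 to 2.338 in the other arrays. Because it varied with somite number, the lower count does not separate stage from this SD. Without WT 3, WT 4, mutant 1 or mutant 4, 1 or 2 genes passed.

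As sets, 6 lists passed the camera test for the slope at the preset correlation. With an estimated correlation 0 lists were called, with an adjusted p of 0.644 for 5 of the 6 and 0.686 for the receptors. Slopes were positive for oxidative phosphorylation (64 of 77 members above 0, adjusted p 8.51e-05), cell cycle (25 of 29, 0.000346) and proteasome genes (27 of 39, 0.00149). Slopes were negative for hindgut endoderm markers (1 of 14 above 0, 0.00149), Hox genes (4 of 37, 0.00752) and the olfactory and vomeronasal receptors (349 of 1178, 0.0320). The mitotic kinase Cdk1 had a slope of 0.28 ± 0.04, the spindle checkpoint kinase Bub1b 0.15 ± 0.04 and cyclin E1, Ccne1, 0.17 ± 0.07. Among hindgut markers the epithelial keratins Krt18 and Krt19 had slopes of -0.41 ± 0.09 and -0.19 ± 0.06, and Ttr -0.16 ± 0.06. Hoxb6, Hoxd4 and Hoxa6 had slopes of -0.16 ± 0.05, -0.16 ± 0.06 and -0.15 ± 0.05. Adjusted over the list alone, 1 cell cycle gene (Cdk1, 0.00299) and 1 hindgut marker (Krt18, 0.0240) passed, and 0 passed over all genes.

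For the other named members, slopes were 0.15 ± 0.06 for Ndufb11, 0.14 ± 0.06 for Ndufb6, 0.14 ± 0.05 for Ndufs7, 0.17 ± 0.05 for Psmc6, 0.15 ± 0.06 for Psmd13 and 0.12 ± 0.05 for Psmc1. The receptors Vmn2r83, Olfr572 and Olfr676 had slopes of -0.23 ± 0.05, -0.22 ± 0.05 and -0.17 ± 0.04. With the SD of unnamed probes as a covariate 0 lists were called, but this SD varied with somite number, so the result does not separate it from stage. With the Y-linked mean as a covariate 1 list, the Hox genes, was called. The arrays of low Y-linked mean, WT 3 and mutant 4, had midpoints of 22 and 21.5 somites, so this covariate overlaps with stage too. Without WT 1, an embryo of 25 somites, 2 lists were called, oxidative phosphorylation and hindgut endoderm. Without WT 4, an embryo of 21 somites, 13 lists were called, the 6 among them. After quantile normalization 2 lists were called, hindgut endoderm and, from outside the 6, extracellular matrix.

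Variation between embryos was compared between the genotypes. The mean correlation of an array with the other arrays of its group was 0.969 ± 0.00228 in WT and 0.976 ± 0.00276 in mutants (SD, n = 4), lower in all 4 WT arrays than in all 4 mutant arrays. The exact two-sided permutation test gave p = 0.0286, the smallest that groups of 4 can give. These correlations share pairs of arrays and are not independent, and when they were computed anew for each of the 35 splits of the arrays, 6 splits gave a difference of group means as large. The median SD over genes was 0.245 in WT and 0.209 in mutants, and the ratio of the median variances was 0.728. Without WT 3 this ratio was 0.930 and the permutation p was 0.171, and without WT 4 the p was 0.114.

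**Figure D3:**
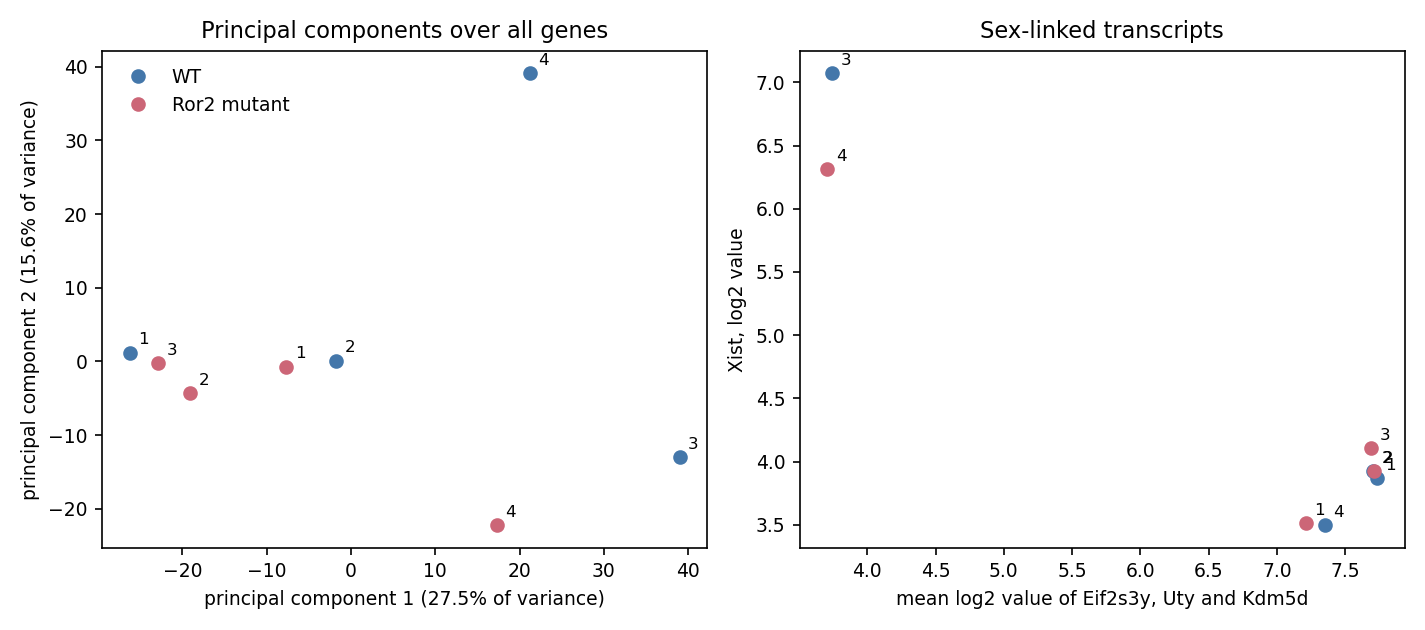
Left, the 8 arrays (points, numbered by replicate) on principal components 1 and 2 of all genes, which hold 27.5% and 15.6% of the variance. Right, the log2 value of Xist against the mean log2 value of Eif2s3y, Uty and Kdm5d, where WT 3 and mutant 4 stand apart from the other 6 arrays.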

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

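The tests below of the host gene Eef2 and of the other small nucleolar RNAs were chosen or settled only after the result was seen. So was the use of quantile normalization to test an explanation, although the normalization itself was planned. The covariate for the spread of unnamed probes and leaving out WT 3 and mutant 4 together were also chosen only then.

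At the preset correlation, genes of energy metabolism and ribosomal proteins were called higher and receptor genes lower in mutants, but with an estimated correlation all 4 lists had an adjusted p of 0.796, with fry 0.840, and 0 members passed. Chance cannot be excluded, since 15 of the 35 splits of the arrays called as many as the 4 lists and the highest other split called 14. Adjusting for stage did not remove the calls: 4 of the 4 lists stayed called with the somite midpoint as a covariate. The mean differences were then 0.17 ± 0.07 (SE) for oxidative phosphorylation and 0.26 ± 0.10 for glycolysis. As this test called lists in many splits, it cannot exclude other effects of stage. The distribution of values is a candidate explanation, since 0 stayed called after quantile normalization. The mean difference of oxidative phosphorylation went from 0.15 ± 0.08 (SE) to 0.08 ± 0.04 and that of glycolysis from 0.25 ± 0.09 to 0.18 ± 0.06. That of ribosomal proteins went from 0.07 ± 0.05 to 0.01 ± 0.02 and that of receptors from -0.09 ± 0.06 to -0.03 ± 0.01. Relative to its SE, only the difference of ribosomal proteins fell, so the lost calls do not decide this for the other lists. The distribution was not tested by the covariate of unnamed probes, which left 0.18 for oxidative phosphorylation, because their SD was highest in WT 3 (2.34) where that of genes was lowest (1.77). WT 3 as the sole source cannot be told apart from a difference of genotype, which stays open: 0 stayed called without WT 3, with differences of 0.09 ± 0.07 for oxidative phosphorylation and 0.21 ± 0.10 for glycolysis, but 3 did without WT 3 and mutant 4 together, with 0.14 ± 0.05 and 0.28 ± 0.07.

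Snord35b and Snord37 had higher values in mutants and Snord42b lower ones (-1.48), each passing only when adjusted over the list alone (limma adjusted p over all genes of 0.246, 0.973 and 0.973). The 49 small nucleolar RNAs other than Snord35b and Snord37, with Snord42b among them, had a median difference of -0.35 ± 0.12 (SE over RNAs, not over embryos). The mean of the whole list was 6.52 to 6.73 in mutants 1, 3 and 4, 7.33 in mutant 2, and 6.90 to 7.01 in WT. A general gain of small RNAs is thus argued against for mutants 1, 3 and 4, but not for mutant 2. Small nucleolar RNAs of this kind are processed from introns, so the level of the host gene was examined for Snord37. The host Eef2 differed by 0.0611 with a 95% interval from -0.23 to 0.35, while Snord37 differed by 2.87. A matching rise in the level of Eef2 is thus argued against. That level does not measure transcription or the processing of introns, which stay open. The host was examined for Snord37 alone, and cross-hybridisation or strain variants under the probes may remain as causes that no test addressed.

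WT arrays were less alike than mutant arrays. Chance cannot be excluded: 6 of the 35 splits gave a difference of mean correlations as large as the real 0.00729, and the highest other gave 0.0122. The difference without WT 3 was 0.00456, larger than the bound set for an effect of WT 3 alone, but the arrays of the groups then overlapped, so the pattern cannot be told apart from the effect of that 1 array. No biological explanation was tested. The wider range of stages in WT, with 21 to 25 somites against midpoints of 21.5 to 24 in mutants, was not tested as a cause either.

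Single embryos stood apart from the other 3 of their group in 13 of 310 groups of values examined, where chance gives 15.5, and 5 of the 13 were in mutant 4 and 3 in WT 3. Ror2 was 7.38 in WT 2 against 7.76 to 7.83 in the other WT arrays. Tpi1 was 8.85 in mutant 2 against 9.02 to 9.05. Rpl19 was 12.18 in mutant 4 against 12.33 to 12.34. Tyrobp was 6.54 in WT 1 against 5.79 to 5.90. Krt18 was 9.47 in WT 4, the WT embryo with the fewest somites, against 7.37 to 7.70. Spink1 was 6.50 in mutant 4 against 3.56 to 3.85, and the mean of the hindgut endoderm list there was 6.20 against 5.61 to 5.69. Hmga2 was 7.10 in mutant 4 against 6.32 to 6.39. Xist was 7.07 in WT 3 against 3.50 to 3.92, and the mean of the Y-linked list there was 3.85 against 5.48 to 5.57. The FGF and ERK list had a mean of 7.34 in WT 3 against 7.50 to 7.53, and the migration and adhesion list 7.42 in WT 2 against 7.33 to 7.34. The mean correlation of mutant 4 with its group was 0.972 against 0.977 in each of the other 3.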

How the results depend on the processing

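The covariate of unnamed probes and leaving out WT 3 and mutant 4 together were chosen only after the result was seen. The count of 0 genes for mutant against WT held in all 21 alternatives. Genes at an unadjusted p under 0.05 numbered 538 of the brighter genes (fewer tested), 1609 of all probes (more tested), 1664 with the covariate of unnamed probes, and 729 to 1715 when leaving out each array (1715 without WT 1). List calls numbered 7 with the somite covariate, 7 with that of unnamed probes, 0 after quantile normalization, 0 with an estimated correlation, 0 with fry, and 0 (without WT 3) to 7 (without WT 1) when leaving out each array. The 3 lists added in each setting with 7 were proteasome, cell cycle and primitive erythroid, and small nucleolar RNAs were called among the brighter genes (0.0139) and without mutant 2 (0.00382). The direction of 17 of the 34 lists, none of the 4 called, turned in at least 1 alternative, among them actin cytoskeleton after quantile normalization (0.974). For the somite slope, 0 to 2 genes passed when leaving out each array: 1 without WT 3 (Podxl), 2 without WT 4 (Fmr1nb, Snora16a), 1 without mutant 1 (Gdap10) and 1 without mutant 4 (Commd6), all named after their values were seen. Genes with a slope at an unadjusted p under 0.05 numbered 1046 of the brighter genes and 708 with the covariate of unnamed probes, which itself varied with somite number. The p for the spread went from 0.0571 to 0.171, and 0.0571 is the smallest that 3 against 4 can give. The cause was not tested except where named. The p for genes near Ror2 stayed between 0.330 and 0.987. With the replicate block, 891 genes had an unadjusted p under 0.05 and 4 lists were called. The residuals of same-numbered embryos correlated from -0.194 to 0.0965, within the range of the other pairs (-0.268 to 0.248). No shared effect of the number was seen, but this cannot show whether the embryos were paired, which the labels do not say. Signal over background could not be judged from these values.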

Other observations

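The analyses of array structure and of unnamed probes in this part were chosen only after the results were seen, apart from the splits of the arrays.

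For the slope per somite, 9 genes of 6 lists passed adjusted over the list alone and 0 over all genes, and those below were named after their values were seen. Slopes were positive for Tcl1, a coactivator of Akt kinase in germ cells (0.50 ± 0.10 log2 per somite, SE, limma adjusted p 0.0231), the Wnt receptor Fzd3 (0.49 ± 0.08, 0.00803), Snord33 (0.62 ± 0.13, 0.0226) and Snord15b (0.46 ± 0.07, 0.00692). They were negative for Trim71, a partner of the let-7 pathway (-0.27 ± 0.07, 0.0450), and for the BMP targets Hand1 (-0.19 ± 0.05, 0.0380) and Gata3 (-0.17 ± 0.05, 0.0380). The lists of extracellular matrix (5 of 23 members above 0, limma camera adjusted p 0.0501), urogenital mesoderm (1 of 10, 0.101) and endothelium (2 of 14, 0.121) had mostly negative slopes and did not pass, although extracellular matrix passed after quantile normalization. Neural crest genes had 0 of 8 members above 0 (0.242). Noncanonical Wnt and planar polarity genes had 13 of 38 above 0 (0.680).

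The first principal component followed the SD of log2 values over genes within each array, with Pearson's r of -0.989 (exact permutation p = 2.48e-05, the smallest that 8 arrays can give, adjusted 7.44e-05 over 3 relations) and Spearman's rho of -1.0 (p = 4.96e-05, adjusted 0.000149). Leaving out WT 3 and WT 1 gave r of -0.975. The somite midpoint correlated with the component at r of -0.636 (exact permutation p = 0.0949, adjusted 0.142) and rho of -0.671 (p = 0.0770, adjusted 0.0770), and r was -0.648 without WT 1 and WT 2. With the SD it correlated at r of 0.544 (exact permutation p = 0.161, adjusted 0.161) and rho of 0.671 (p = 0.0770, adjusted 0.0770), and r was 0.621 without WT 1 and WT 2.

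For genes at an unadjusted p under 0.05, 10 of the 35 splits of the arrays gave as many as the real 934, so chance cannot be excluded. The highest other split gave 3219 genes and parted WT 1 and mutants 1, 2 and 3, whose SD over genes ran from 1.90 to 1.95, from the other 4 arrays, at 1.77 to 1.86. That count was over 3 times the real one. The split was picked as the highest, and no value expected by chance was set for such a pick, so no conclusion is drawn from it. The split keeps 6 of the 8 arrays on the side of their genotype, so width, genotype and stage were not separated by it. For the genes near Ror2, 22 of the 35 splits gave a camera p as small as 0.642, and the smallest other was 0.103, so chance cannot be excluded. Of the 12147 unnamed probes, 698 (5.75%) had an unadjusted p under 0.05 for mutant against WT, and 0 passed in limma.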
